A study of Mus musculus with 8 samples.

How the data were processed

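RNA of CD31-bearing cells from 8 mouse embryos (E12.5, C57Bl/6J background) was measured, 4 Gata2 +9.5 mutants and 4 wild type littermates from 2 litters, with 1 array per embryo. Per the labels' protocols, cells were taken from embryos without liver and brain, dissociated with collagenase and enriched with magnetic beads, and cRNA labelled with Cy3 was made from 0.1 ug of RNA. The deposited scanner files give the intensity of each spot on a linear scale. Per the file headers they were made with Agilent Feature Extraction 10.7.3.1 on 1 channel with the mm9 annotation, and the processed intensity is background-subtracted and detrended within the array, with a surrogate in place of low signals. No normalization between arrays had been applied to these intensities.

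The authors' deposited table gives log2 values for the 8 samples and the log2 fold change, with a p-value and an adjusted p-value for each probe. It was made with limma, per the submitters' processing notes, which give no version. Set against the scanner files, each column of the authors' deposited table lies close to the array's log2 signal minus the median of its non-control spots. Its column medians run from -0.11 to -0.07 in the authors' deposited table, and its direction is mutant over wild type. The authors' deposited table has 50120 non-control probes and leaves out 5561 of the non-control probes of the scanner files. In the authors' deposited table the fold change divided by its t is the same number for each probe, 0.555 at the median, so the p-value there rests on 1 spread shared by all probes. It served as an alternative source of values.

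From the scanner files, log2 of the processed intensity minus each array's 75th percentile over non-control spots was taken. Control spots and spots marked as outliers by the scanner software (130 to 521 per array) were left out, and spots of a probe were averaged, which gave 55681 probes. Probes well above background on at least 4 of the 8 arrays were kept (48121), and the brightest probe stood for each gene symbol. Of the probes, 26756 were named through their RefSeq accession, 3824 by a symbol or synonym in the reference gene table, 2683 kept the name in the file and 22418 had no name and stayed as features of their own. The 40477 features (22037 with a symbol) had at least 3 values per group, 715 of them with a missing spot. A probe not well above background on any array of a group has only a bound there. Its fold is given as "at least", from the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own. The median change of all features was 0.05. Over 432 probes spotted repeatedly on each array, the median SD of log2 signal was 0.102 to 0.178, and 74.9% to 92.0% of spots were well above background.

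Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over all features, threshold 0.05), with genotype as the term and no covariate. Litter differences were tested with genotype in the model, and the difference of the genotype effect between litters with an interaction term. Litter holds both genotypes and is a shared litter per the labels, so results with litter as a block are given where they change a call. The arrays of a litter share a slide, so no separate slide block was run. Gata2 and the levels of gene lists were also tested with exact permutation of 4 against 4 arrays, without regard to litter and without adjustment over lists. Genes near Gata2 were compared with Fisher's exact test.

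The 26 lists of cell type markers, functions and neighbours of Gata2 were fixed before the data were examined. So were the comparisons, the other settings to be tried and the rule for naming genes. The rule names Gata2, the 10 genes with the largest fall and rise past the threshold that are well above background in at least 1 group and do not overlap between groups, and up to 4 members of each list past the threshold. Where none passes it names the 2 brightest members, and it adds the sex chromosome genes as a check. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 26 lists. Some genes stand in more than 1 list, such as Itga2b in the platelet and the stem and progenitor lists.

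The fit was tested on simulated data with the real means and spreads of 39762 features for the genotype comparison. Of 67 genes changed by 1 log2 unit 0 were recovered, of 67 changed by 2 log2 units 10 (14.9%), and of 66 changed by 3 log2 units 42 (63.6%), with 1 unchanged gene called. A simulated list with lower genes was found by camera at the preset correlation (adjusted p = 4.06e-17) and 0 unchanged lists were called. The simulated noise was independent between genes and between arrays. It therefore cannot show how the preset-correlation test behaves for members that vary together, as in the real lists (estimated correlation 0.91 for pan-endothelial genes).

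Alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization, the median of each array, the authors' values, no filter and a filter on all 8 arrays, a floor of 5 on the log2 scale, all probes or the mean of probes of a gene, an intensity trend with robust variance, litter as a fixed or random block, sample number as a block, each litter alone, other thresholds and windows, and leaving out each array in turn. For the weighted, trend and random-block fits the preset-correlation test was run on the statistics of that fit. Array quality weights, leaving out 3 arrays, a covariate for Xist signal, leaving out 2 wild type arrays and the interquartile range as a covariate were added after the data were seen. Figures were drawn with matplotlib 3.10.9.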

Results

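Gene expression was measured on one-colour microarrays in cells bearing CD31 (PECAM-1), an adhesion protein of endothelial cells that platelets and many leukocytes also carry. The cells came from mouse embryos at stage E12.5, 4 homozygous for a mutation of the Gata2 +9.5 enhancer and 4 wild type littermates. This enhancer lies in an intron of Gata2, which encodes a zinc-finger transcription factor needed for the formation of blood stem cells. The 8 embryos belonged to 2 litters with 2 embryos of each genotype in each, and the arrays of each litter shared a slide, so litter and slide are the same grouping here. Samples 1 and 2 of each genotype are from litter 1, samples 3 and 4 from litter 2. Each array held 62976 spots, of which 74.9% to 92.0% of the non-control ones were well above background, and the 75th percentile of the signal ran from 996 to 2481. Log2 values of the arrays correlated across genes at r = 0.892 to 0.980, genes not being independent replicates. The precision of every value below is limited by the number of arrays. Values are log2 signals relative to each array's 75th percentile, and changes are mutant minus wild type.

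The arrays did not differ by genotype alone. The first principal component, with 58.8% of the variance, set wild type 2 (100), wild type 3 (159) and mutant 4 (125) apart from the others (-128 to 23). The interquartile range of the log2 signal ran from 2.91 on mutant 4 to 4.39 on mutant 2. Principal component 2 held 19.2% of the variance and was 51 or more on 3 of the 4 litter 2 arrays, against -28 or less on the litter 1 arrays and on wild type 3.

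**Figure D1:**
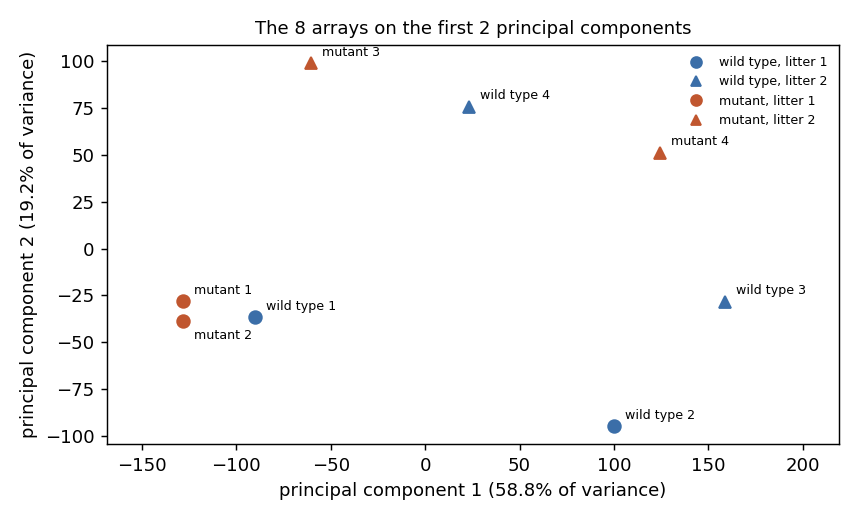
The 8 arrays on principal components 1 and 2 of the log2 signal (axes: component scores, with the percent of variance). Colour gives the genotype and shape the litter. Wild type 2, wild type 3 and mutant 4 lie at 100 or more on component 1.

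Gata2 itself was examined to check the labels and to give the level of the gene whose enhancer was mutated. Its measured probe lies on chromosome 6 from 88156362 to 88156421 (mm9, per the file headers) and reads the transcript, not the mutated element. Gata2 was at 1.49 ± 0.46 (SD, n = 4) in wild type and -0.93 ± 0.53 (SD, n = 4) in mutant cells, a difference of -2.42 ± 0.39 (SE), or 5.36-fold lower. All 4 mutant values lay under all 4 wild type values. The difference was -2.52 in litter 1 and -2.32 in litter 2. The exact two-sided permutation p was 0.0286, the smallest that 70 arrangements allow. Over all features, limma's adjusted p was 0.0865 (unadjusted 6.59e-05), so Gata2 did not pass the threshold of 0.05; over the alternatives its adjusted p ran from 0.00870 to 0.998, and 5 of 29 passed.

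The central comparison asks which genes differ in CD31-bearing cells when the enhancer is mutated. Among genes past the adjusted threshold, the 10 that fell by most include products of granulocytes, mast cells and platelets. Stfa1, a stefin of neutrophils, fell by 5.58, with 2 of 4 mutant arrays well above background, and ran from -6.19 to -4.31 over the alternatives. S100a9 fell by 4.93 and S100a8 by 3.98, the paired calcium-binding proteins of neutrophils. Mpo, the myeloperoxidase of granulocyte precursors, fell by 4.88 (-3.66 in litter 1, -6.11 in litter 2, and -5.61 to -4.50 with single arrays left out), and Rnase2a, an eosinophil-associated ribonuclease, by 3.52. Ear2 of the same family fell by 5.43, with 1 of 4 mutant arrays well above background, and ran from -6.42 to -3.67 over the alternatives. For Stfa1, Ear2, S100a8, Rnase2a and Slpi some mutant values lie near background, so the size of the fall is uncertain. Treml1, a receptor of platelet granules, fell by 3.70 (13.0-fold lower). Hdc, which makes histamine, fell by 3.53, Slpi, a protease inhibitor, by 3.52, and Cstdc5, another stefin-like gene, by 3.49. The SEs of these 10 genes ran from 0.41 (Cstdc5) to 0.76 (Ear2), with n = 4 per group. Their adjusted p in limma ran from 0.0234 to 0.0486, and for each all 4 mutant values lay under all wild type values. The rule for naming required the threshold and the lack of overlap, so neither is added support.

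In all, 17 of 40477 features passed limma's adjusted p of 0.05, 17 lower and 0 higher in the mutants; at an unadjusted p under 0.05 there were 1240 (155 higher, 1085 lower), where 2024 would be expected if no gene differed. The other 7 were Gp9, Gp1ba, Slamf1, AI661384, Prg2, Rab44 and Ly6g6f, the last 4 of them named after their values were seen; Prg2, the major basic protein of eosinophils, was at -3.33, AI661384 at -3.48, Rab44 at -3.22 and Ly6g6f at -2.86. Stfa1, Cstdc5, Ear2 and Rnase2a belong to families of near-identical paralogs, so a probe may read several of them. With litter as a block 0 features passed in limma (1968 at an unadjusted p under 0.05; the lowest adjusted p was 0.0537), while the fold changes stay the same because the litters are balanced. The count also fell to 6 without wild type 2, and in limma to 0 without wild type 1 (4037 at an unadjusted p under 0.05), wild type 3 (378), wild type 4 (1827), mutant 1 (501) or mutant 3 (478). Without wild type 2, wild type 3 and mutant 4 together it was 0 as well (2222 unadjusted). The fold changes themselves stayed about as large with single arrays left out, from -6.19 to -5.07 for Stfa1, -4.06 to -3.53 for Treml1 and -3.01 to -2.55 for Gp1ba.

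**Figure D2:**
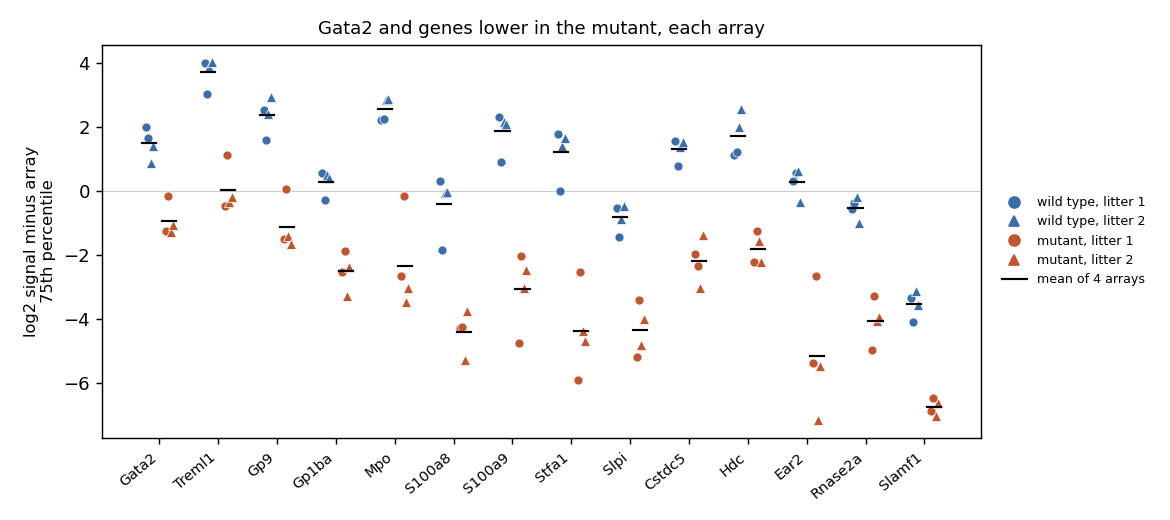
Log2 signal relative to each array's 75th percentile (vertical axis) for Gata2 and the genes named by rule that fell, on each of the 8 arrays. Points are arrays, colour gives the genotype, shape the litter, and bars the mean of 4 arrays. Each gene shown is lower on all 4 mutant than on all 4 wild type arrays, as the rule required of the genes with the largest fall. Slamf1 was not well above background on the mutant arrays.

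Platelet and megakaryocyte genes were lower together. Treml1, Gp9 and Gp1ba passed over all features: Gp9 and Gp1ba, subunits of the platelet receptor for von Willebrand factor, fell by 3.49 ± 0.46 and 2.80 ± 0.39 (SE, n = 4 per group). All 21 measured members of the list were lower in the mutants, 18 without overlap between the groups, and 18 passed when adjusted over the list alone against 3 over all features. Pf4 and Ppbp, chemokines of platelet granules, were at -2.75 and -3.30, and Itgb3, a platelet integrin, at -3.44; these 3 passed over the list alone and were named after their values were seen. The median of the list was -2.15, or 4.45-fold lower, with -2.07 in litter 1 and -2.55 in litter 2. The list fell against all other genes by camera (adjusted p = 5.36e-37), and adjusted p = 0.0397 with an estimated correlation.

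Granulocyte and mast cell genes also fell as groups. Of 15 granulocyte genes 12 were lower and 3 fell over all features (S100a9, Mpo and S100a8), against 7 adjusted over the list alone; the median was -1.01 (-1.11 in litter 1, -0.86 in litter 2, and -0.68 with normexp and quantile normalization). Camera gave adjusted p = 2.43e-10 for this list, and adjusted p = 0.0569 with an estimated correlation, so that call was lost. Of 13 mast cell genes 10 were lower and 1, Hdc, fell over all features. Adjusted over the list alone 5 fell: Hdc, Cpa3, the mast cell carboxypeptidase (-4.92), Il1rl1, the receptor of interleukin 33 (-2.17), Cma1, a chymase (-1.58), and Srgn, the core protein of granule proteoglycans (-1.31); the last 4 were named after their values were seen. The mast cell median was -1.31 (-0.98 in litter 1, -0.94 in litter 2; camera adjusted p = 2.07e-08, and adjusted p = 0.0397 with an estimated correlation). It was -0.77 with a floor, with all probes or with the filter on all 8 arrays, and -0.62 with normexp and quantile normalization.

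Among genes of leukocytes in general 16 of 18 were lower, with a median of -0.95 and a camera adjusted p of 2.07e-08, but adjusted p = 0.101 with an estimated correlation. No member passed over all features; adjusted over the list alone 1 fell, Cytip (-1.94), a regulator of leukocyte adhesion named after its value was seen. The brightest members went both ways, Lcp1, an actin-bundling protein, at 0.33 and Arhgdib, a signalling protein of blood cells, at -0.18. Of 29 genes of hematopoietic stem and progenitor cells 18 were lower and the median was -0.34 (camera adjusted p = 2.71e-04, and adjusted p = 0.220 with an estimated correlation). Slamf1, a surface marker of blood stem cells, was the member that fell over all features. It was well above background on no mutant array and at least 2.60-fold lower (1.38 in log2) with the main processing (limma adjusted p = 0.0234). Over the alternatives Slamf1 ran from -3.49 to -0.91, so that bound does not hold in each of them, and it passed in 12 of 28. Adjusted over the list alone 4 fell, among them Slamf1, Itga2b (-2.45), which the platelet list also holds, and Gfi1 (-1.89), a transcriptional repressor in blood cells, the last 2 named after their values were seen. The median of this list was -0.13 with all probes, and without mutant 4 it was -0.12 relative to all features (adjusted p = 0.0933).

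Macrophage, erythroid and lymphoid genes were compared next. Of 25 macrophage and monocyte genes 22 were lower, with a median of -0.29 (adjusted p = 0.0256, and adjusted p = 0.752 with an estimated correlation); Csf1r, the receptor that sustains macrophages, was at -0.23 ± 0.51 (SE) and Itgam, an integrin of myeloid cells, at 0.27. The macrophage call was lost without mutant 1 (adjusted p = 0.507), mutant 4 (0.0683), wild type 3 (0.131) or wild type 4 (0.363). With single arrays left out this list ran from -0.58 to -0.017 relative to all features. Erythroid genes had a median of 0.37 (adjusted p = 0.242; 0.0448 with litter as a block; adjusted p = 0.752 with an estimated correlation), with the embryonic globin Hbb-y at 0.51 and the adult globin Hba-a1 at 0.38. Adjusted over that list alone 1 rose, Add2 (1.47), a protein of the red cell skeleton, and 1 fell, Gata1 (-1.76), the transcription factor of red cells and megakaryocytes; both were named after their values were seen. Lymphoid genes had a median of -0.45 (adjusted p = 0.0757), with Lck, a T cell kinase, at -0.16 and Thy1 at 0.45. With single arrays left out the lymphoid list passed in 4 of 8 fits (-0.64 to -0.25 relative to all features, lowest adjusted p 0.0217) and the erythroid list in 3 of 8 (0.0049 to 0.55 relative to all features). The level of a list (the median of its members on an array) was tested by exact permutation of the arrays. It differed for the platelet (-2.30), granulocyte (-1.06), mast cell (-1.19) and leukocyte (-1.01) lists, each with permutation p = 0.0286, the smallest possible. For the stem and progenitor list that p was 0.0571 and for the macrophage list 0.486. The macrophage level ran from -1.25 to -0.35 in litter 1 and from 0.43 to 0.95 in litter 2. The permutation ignores litter, so 0.486 does not show that macrophage genes were unchanged. With litter as a block, camera at the preset correlation gave adjusted p = 8.67e-04 for the macrophage list, downward.

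**Figure D3:**
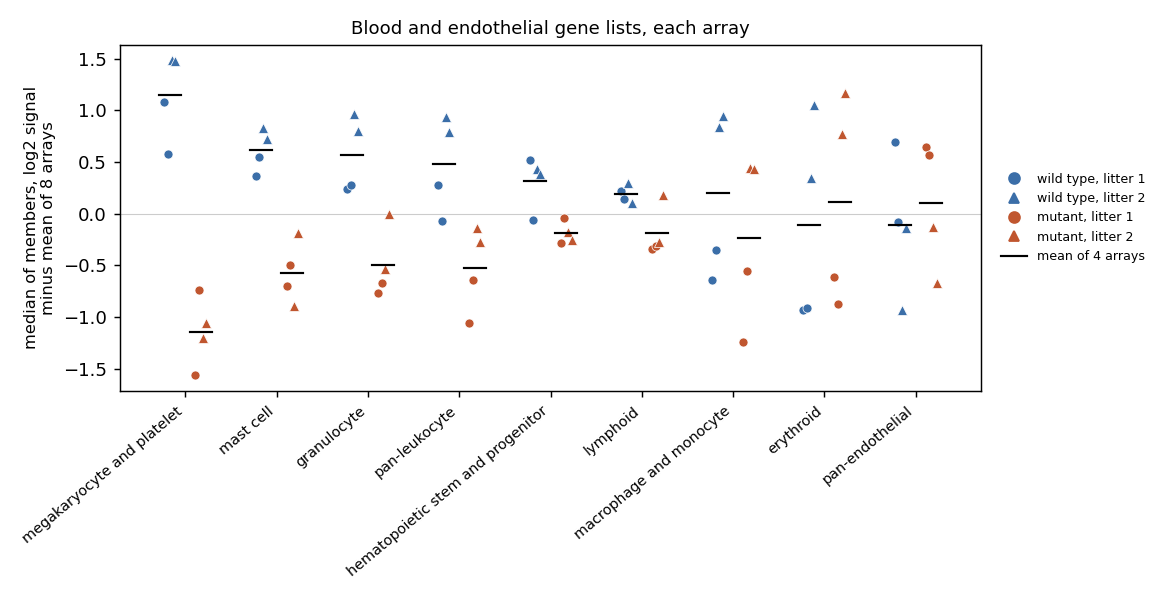
Level of 9 blood and endothelial gene lists on each array: the median over members of the log2 signal minus each gene's mean over the 8 arrays (vertical axis). Points are arrays, colour gives the genotype, shape the litter, and bars the mean of 4 arrays. In the platelet, mast cell, granulocyte and leukocyte lists the 4 mutant points lie under the 4 wild type points.

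Endothelial genes, the main content expected from a CD31 enrichment, showed no gene past the threshold over all features. Of 30 pan-endothelial genes 23 were higher in the mutants, with a median of 0.24 (adjusted p = 0.0502; 0.0308 with litter as a block; adjusted p = 0.752 with an estimated correlation). The brightest members were Egfl7, a secreted endothelial factor, at 0.14 ± 0.47 (SE, n = 4 per group), and Cd93, an endothelial surface lectin, at 0.23 ± 0.46. This list turned to -0.15 relative to all features with quantile normalization (adjusted p = 0.0204) and to -0.14 with normexp and quantile normalization (0.0123), so it has no settled direction; it passed in 4 of 8 fits with single arrays left out. Its level followed principal component 1 over the 8 arrays (r = -0.910, exact permutation p = 0.00295, and rho = -0.857, exact permutation p = 0.0107). Adjusted over 4 relations these p were 0.00394 and 0.0143, and r was -0.778 without the 2 arrays farthest from the median. The members are among the features behind the component, so this relation describes the arrays and does not test endothelial content. Relative to 2888 genes of the same brightness, r was -0.301 (exact permutation p = 0.454). Each litter holds 4 arrays, too few for a value within litters.

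The arterial list had a median of 0.31 (adjusted p = 0.243), with the connexin Gja4 at 0.44 and the ephrin Efnb2 at 0.62. Relative to all features it lay at -0.02 with quantile normalization. Adjusted over the list alone 1 of its 17 members fell, Alox12 (-2.53), which is a lipoxygenase of platelets and was named after its value was seen. The venous list was at 0.28 (adjusted p = 0.120; Nrp2 at 0.66, Aplnr at 0.61) and the lymphatic list at 0.33 (adjusted p = 0.0549; 0.0479 with litter as a block; adjusted p = 0.684 with an estimated correlation), with Tbx1, a transcription factor of pharyngeal and lymphatic development, at 1.12. With single arrays left out, the arterial and venous lists passed in 2 of 8 fits each and the lymphatic list in 3.

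Several lists of other cell types and cell states were shifted by the preset-correlation test, and none of them with an estimated correlation. Cell cycle genes were higher in 17 of 18 cases, with a median of 0.45 (adjusted p = 2.61e-04); Mcm6 of the replicative helicase was at 0.41 and Birc5, a mitotic regulator, at 0.39. Hypoxia and glycolysis genes had a median of 0.40 (adjusted p = 0.00502), with the glycolytic enzymes Ldha and Aldoa at 0.36 and 0.46. For both lists, and for epithelial, neural and Gata2 neighbour genes, adjusted p = 0.684 with an estimated correlation. Both calls were lost with quantile normalization (adjusted p = 0.147 for the list cell cycle and 0.263 for the list hypoxia and glycolysis), and the hypoxia call without mutant 1 (0.0565). By exact permutation of the arrays, p was 0.229 for the cell cycle level and 0.257 for the hypoxia level. Both levels were lowest on wild type 3 (-0.74 and -0.61), wild type 2 (-0.55 and -0.50) and mutant 4 (-0.36 and -0.33), the arrays apart on principal component 1. With single arrays left out the lists ran from 0.22 to 0.76 and from 0.14 to 0.66 relative to all features. Neural and neural crest genes were at 0.32 (adjusted p = 0.0233; Snap25 at 0.28, Gap43 at -0.20) and epithelial genes at -0.59 (adjusted p = 0.0233), the latter with 10 of 14 lower and the keratins Krt18 at 0.08 and Krt5 at -0.64. The neural call was lost without wild type 1 (adjusted p = 0.161), wild type 2 (0.165) or mutant 3 (0.172), and the epithelial call without wild type 3 (0.0959) or wild type 4.

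The remaining lists did not pass with all 8 arrays. Immediate early and heat shock genes had a median of 0.26 (adjusted p = 0.0757; Jun at 0.26, Nr4a1 at 0.26), interferon response genes 0.43 (adjusted p = 0.120; Bst2 at 0.63, Ifitm3 at 0.54), and mesenchyme and pericyte genes 0.09 (adjusted p = 0.201; the collagens Col1a2 at 0.17 and Col3a1 at 0.41). Skeletal muscle genes were at 0.27 (adjusted p = 0.360; Tnnt1 at 0.59, Actc1 at 0.62), cardiomyocyte genes at -0.39 (adjusted p = 0.509; Tnni3 at -0.79, Myh6 at -0.64) and cartilage genes at -0.01 (adjusted p = 0.842; Col2a1 at 0.05, Hapln1 at 0.10). With single arrays left out, calls were gained in 3 of 8 fits for the interferon list, which turned to -0.21 relative to all features without mutant 1, in 3 for GATA factors, in 2 for immediate early and in 1 for mesenchyme genes. Immediate early and mesenchyme genes had a negative median relative to all features with quantile normalization (-0.16 and -0.03). Leukocyte adhesion and inflammation genes had a median of 0.09 but a mean of -0.16, and the test ran downward (adjusted p = 0.495); Madcam1 was at -0.40 and Cxcl12 at 0.39. Adjusted over that list alone 1 fell, Il6 (-2.03), a cytokine named after its value was seen, and fry's test for change in either direction gave adjusted p = 3.74e-04. GATA factors and cofactors had a median of 0.43 (adjusted p = 0.112) with the adaptors Lmo2 at 0.62 and Ldb1 at 0.25; Gata1 was the 1 member of 10 that fell, adjusted over that list alone.

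A targeted allele can carry flanking sequence of another strain, so genes around Gata2 were compared with the rest. Of 546 features within 20 Mb of Gata2 on chromosome 6, 1 (Gp9) passed the threshold, against 16 of 39491 elsewhere (Fisher's exact two-sided p = 0.208). The list of 14 genes near Gata2 had a median of 0.38, with Rpn1, a subunit of oligosaccharyltransferase, at 0.29 and Cnbp at 0.51. Camera gave adjusted p = 0.0233 for the list genes near Gata2, a call that was lost without mutant 1 (0.0565) or mutant 2 (0.0563) and with quantile normalization (0.367). It was also lost with an estimated correlation (adjusted p = 0.684). The level of this list was lowest on wild type 3 (-0.63), wild type 2 (-0.50) and mutant 4 (-0.16), the arrays apart on principal component 1.

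Litter was compared to learn what a block on it removes. With genotype in the model 1971 features differed between litters, 1613 higher and 358 lower in litter 2, by limma's adjusted p. That count ran from 4 without mutant 2 to 3854 without wild type 2. It was 25 without mutant 1, 215 without mutant 3, 593 without mutant 4, 514 without wild type 1 and 468 without wild type 4. For the difference of the genotype effect between litters, limma called 0 features (494 at an unadjusted p under 0.05). Hepatocyte genes, a check for liver tissue, had a median genotype difference of -0.12 in litter 1 and 1.85 in litter 2. Over all arrays their median was 0.86 (adjusted p = 0.0549; 0.0233 with litter as a block; adjusted p = 0.752 with an estimated correlation), with the apolipoprotein Apoa2 at 0.71 and the thyroid hormone carrier Ttr at -0.04. The hepatocyte list passed in 4 of 8 fits with single arrays left out, and ran from 0.25 to 1.28 relative to all features in them.

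Genes of the sex chromosomes were read as a check of balance between the groups. Xist, the RNA of the inactive X chromosome, was at -6.74 in wild type 1 and -6.92 in wild type 4, and between -0.27 and 1.48 in the other 6 embryos. The Y-linked gene Ddx3y was at 1.42 and 1.28 in those wild type embryos and at -5.21 or less in the others. Eif2s3y followed the same division (1.45 and 1.21 against -4.91 or less), though wild type 3 was well above background for both genes. Of 2 dim Uty probes 1 was highest on wild types 1 and 4 (-2.89 and -3.09) and the other on mutant 4 (-2.11), and the dim probe of Kdm5d was at -3.91 on wild type 3 against -4.14 and -4.28 on wild types 1 and 4. By Xist, Ddx3y and Eif2s3y, 2 wild type arrays and 0 mutant arrays carried the male pattern, so sex appears uneven between the groups. Without these 2 arrays limma called 0 genes (8654 at an unadjusted p under 0.05), the platelet list stayed at -2.38 relative to all features, and Gata2 was at -2.21. The wild type arrays that remain, wild type 2 and wild type 3, both stood apart on principal component 1. This check therefore does not separate genotype from that component.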

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

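The tests on embryo sex, on the 3 arrays, on an equal loss of all blood cells, on liver tissue, on the signal range and on splits balanced by litter were chosen after the results were seen, and the threshold for listing litter differences was moved from the estimated to the preset correlation after the first gave 0 lists.

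The platelet list fell in the mutants, and the values argue against 4 other readings, each taken alone. With quantile normalization its median relative to all features was -2.19, and with normexp and quantile normalization it was -1.90. Scaling by the median of each array, which the authors' values share, shifts all features of an array alike. It can therefore hardly move this median and does not bear on the question. Without the 2 wild type arrays that lack Xist signal the median was -2.38, and without wild type 2, wild type 3 and mutant 4 it was -2.41. Leaving out the arrays without Xist signal keeps only wild type 2 and wild type 3, which stood apart on principal component 1. Leaving out the arrays that stood apart keeps only the wild types with the male pattern. Uneven sex and the signal range acting together are therefore not argued against. An equal loss of all blood cells is argued against as well, since the level of the platelet list fell by 1.87 more than that of the macrophage list (exact permutation p = 0.0286) and by 2.52 more than that of the erythroid list (p = 0.0286). For the granulocyte list the difference from the macrophage list was -0.63 (exact permutation p = 0.171), so a specific loss and a loss shared with macrophages cannot be told apart for granulocytes, nor for mast cells (-0.76, p = 0.200), with 4 arrays per group. By camera p chance stays open (splits below), although no other split moved the level of the platelet list as far (-2.30, against 1.64 in size at most; exact permutation p = 0.0286, not adjusted over lists); fewer CD31-bearing platelets and progenitors in the mutants may be the source, as a hypothesis.

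Wild type 2, wild type 3 and mutant 4 stood apart on principal component 1. A candidate explanation is a narrower signal range, since the component followed the interquartile range of log2 signal over the 8 arrays (r = -0.908, exact permutation p = 0.00283; rho = -0.929, p = 0.00223; adjusted over 4 relations 0.00394 and 0.00893; r = -0.919 without the 2 arrays farthest from the median). It followed the percent of spots well above background at least as closely (r = 0.947, exact permutation p = 0.00114, rho = 0.905, p = 0.00456, adjusted 0.00394 and 0.00913, and r = 0.881 without these 2 arrays), so range and signal over background are not separated here. Both measures come from the same intensities as the component, so these relations describe the pattern and do not test its source. Wild type 4 had a narrower range (3.56) than wild type 2 (3.69), yet lay at 23 on the component against 100. Whether some of these arrays also held fewer endothelial cells stays open. Relative to genes of the same brightness the endothelial list gave r = -0.301 (exact permutation p = 0.454, rho = -0.429, p = 0.299), and r = 0.304 without the 2 arrays farthest from the median. The sign thus rests on 2 arrays, and the value lies at the edge of the range where this explanation would be argued against. On this relative scale wild type 2 was at 0.32, the highest of the 8 arrays, wild type 3 at -0.14 and mutant 4 at -0.32, the lowest. Mutant 3, which did not stand apart, was at -0.22. A low endothelial level was therefore not shared by the arrays that stood apart.

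Hepatocyte genes were higher in the mutants of litter 2 (1.85) and not in those of litter 1 (-0.12). Liver tissue left on an embryo could account for part of this, although the liver was removed before the enrichment, because 9 of 11 hepatocyte genes had their highest value on mutant 4. On that array Afp was at 5.95, Apoa2 at 3.02 and Alb at 0.11, levels of different probes that do not rank the transcripts. Mutant 3 was raised as well (Afp at 4.43), which a single embryo would not explain. The level of the hepatocyte list was also higher in the litter 2 wild types (0.12 and 0.21) than in those of litter 1 (-1.37 and -0.56). Afp was at 0.43 and 2.17 in the litter 2 wild types, against -6.61 and -1.19 in those of litter 1. Part of the signal thus goes with litter and slide, in wild types too. The genotype effect on this list differed between litters at the preset correlation (adjusted p = 9.02e-08) and not with an estimated correlation (0.774), so an effect of the mutation in litter 2 stays open.

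Other splits of the 8 arrays bear on whether chance can be excluded. Over all 35 splits it cannot for the 17 genes changed, because 3 gave as many, and the highest other gave 20759. That split sets wild type 1, mutant 1, mutant 2 and mutant 3 against the rest and follows principal component 1, and its many calls point to a structure of the samples; the split by litter gave 1974, while the fit with litter as a block called 0 genes (1968 at an unadjusted p under 0.05 in limma). Among the 18 splits with 2 arrays of each litter on each side, the real one gave 17 and the highest other 0, and these are too few for a share under 0.05. Nor can chance be excluded for any list by its camera p. The platelet list (real p 2.06e-38, smallest other 1.09e-55) and the granulocyte list (1.87e-11 against 1.10e-12) were matched in 2 of 35 splits each, and the mast cell list (3.06e-09 against 9.00e-15) and the leukocyte list (3.18e-09 against 1.39e-16) in 3. The smallest other value of each of these 4 lists came from exchanging wild type 2 with mutant 2. The stem and progenitor list was matched in 6 (6.25e-05 against 3.49e-14), Gata2 neighbours in 5 (0.00813 against 0.00250), epithelial genes in 8 (0.00872 against 1.68e-06), neural genes in 12 (0.00898 against 3.18e-10), cell cycle genes in 13 (5.02e-05 against 8.08e-08), hypoxia genes in 13 (0.00135 against 1.59e-05) and macrophage genes in 18 (0.0108 against 1.77e-19), each count including the real split. For the litter difference 1 of 18 splits gave 1971 and the highest other 0, and these splits are too few for a share under 0.05.

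A value far from the other 3 of its group was found in 9 of 170 groups, where chance gives about 1 in 20. Wild type 2 was low for S100a9 (0.91), S100a8 (-1.84) and Treml1 (3.04). Mutant 2 was high for Gp9 (0.077) and mutant 4 low for Cxcl12 (3.16). Wild type 4 was high for Bst2 (4.23) and for the interferon list (0.74), mutant 4 high for the lymphoid list (0.18) and wild type 1 low for the cardiomyocyte list (-0.37).

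By the interaction test of camera at the preset correlation, the genotype effect differed between litters for 12 of 26 lists, and for 0 of 26 with an estimated correlation (adjusted p = 0.774 for each of the 12). As litter 2 minus litter 1, the difference of medians was 1.96 for hepatocyte, -1.14 for interferon, -0.48 for platelet, -0.39 for hypoxia, -0.31 for arterial and -0.29 for cell cycle genes. It was -0.18 for pan-endothelial, -0.14 for epithelial, -0.14 for adhesion and -0.13 for immediate early genes. For the stem and progenitor list (-0.028) and the mast cell list (0.044) the medians hardly differed.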

How the results depend on the processing

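Array quality weights, leaving out 3 arrays, the Xist covariate, leaving out the 2 wild type arrays without Xist signal and the range covariate were chosen after the results were seen. The platelet and mast cell lists stayed lower and past the threshold in each of 31 alternatives, with medians relative to all features from -2.70 to -1.90 and from -1.45 to -0.65. The granulocyte (-1.34 to -0.71) and leukocyte (-1.13 to -0.68) lists did so in 30 of 31. With an estimated correlation they were at -1.07 (camera adjusted p = 0.0569) and -1.01 (0.101), since correlated members widen the test. Blocks on litter or sample number, a trend, median scaling and the other list tests hardly move a list's median by construction. Most of the 31 also keep the preset correlation, so these counts overstate how independently the lists were tested. The stem and progenitor list passed in 25 of 31 (adjusted p 2.12e-08 to 0.422): it was at -0.39 with an estimated correlation, -0.28 in litter 1 alone, -0.26 with the Xist covariate and without the arrays lacking Xist signal, and turned to 0.016 with array weights. Leaving out single arrays it ran from -0.43 to -0.12. The pan-endothelial list changed sign: it was -0.14 with normexp and quantile normalization, -0.15 with quantile normalization and -0.064 with the range covariate. It was 0.11 with the authors' values, 0.19 with a floor, with a trend, and with litter as a fixed or random block, 0.22 with the mean of probes, 0.39 in litter 1 alone, 0.57 with either Xist setting, 0.89 with array weights, and from -0.065 to 0.64 leaving out single arrays. Interferon genes turned to -0.51 in litter 2 alone. Gata2 passed with the filter on all 8 arrays, a trend and litter as a random block (-2.42 in each), array weights (-2.23) and the range covariate (-2.51); it ran from -2.68 to -2.16 over 29 alternatives. Of genes changed in the mutant there were 31 at an adjusted p under 0.1 and 31 with a trend, 34 with litter as a random block, 29 with the range covariate, 27 with the filter on all arrays, 8 without a filter, 5 with normexp and quantile normalization and 1 with quantile normalization. Of the 17 genes of the main fit, these held 17 with the random block, 17 with the range covariate and 16 with a trend. They held 11 with the filter on all arrays, 8 without a filter, 3 with normexp and quantile normalization and 0 with quantile normalization. With the authors' values there were 52 (12 higher, 40 lower, holding all 17), and with array weights 13720 (4494 higher, 9226 lower). These weights ran from 0.269 to 3.06 and were highest for mutants 1 and 2, so 2 arrays carried most of the mutant mean. There were 0 with litter as a block, in litter 1 alone, without the 3 arrays, with either Xist setting, and with some single arrays left out (0 to 24); limma gave 378 to 11099 at an unadjusted p under 0.05 in the 11 alternatives with 0. Sample number as a replicate block gave 0 genes (1396 unadjusted) and 0.19 for the pan-endothelial list. Deviations of same-numbered embryos correlated at 0.08 on average (-0.16 to 0.62), against 0.45 (-0.08 to 0.74) for the other embryo of the litter. These means rest on 4 pairs each and their ranges overlap. They give no sign that numbers pair the embryos and cannot settle it. The litter block also brought the erythroid, pan-endothelial, lymphatic and hepatocyte lists past the threshold and changed no other list call. Genes differing between litters were 798 with quantile normalization, 998 with the median of each array, 10710 with array weights and 4 to 3854 leaving out single arrays; the genotype effect differed between litters for 4 genes with the authors' values. Scaling by the median moved the median of all features to 0.32 and the authors' values to 0.40, which is why lists are given relative to it. Fisher's p near Gata2 was 0.144 or higher wherever a gene in the window passed; where none did it is 1 by construction and shows nothing. Where no reason is given, the cause was not tested. Dim probes are limited by background: 74.9% to 92.0% of spots were well above it.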

Other observations

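The eosinophil test was chosen after the result was seen. Eosinophil genes, not among the lists fixed beforehand, stood out among those that fell: Ear2 and Rnase2a, ribonucleases of eosinophil granules, and Prg2, the major basic protein. A list of 12 such genes was then written, with the ranked genes already seen. All 12 were lower in the mutants (median -1.66), 7 of them without overlap between the groups. For the 9 that had not passed, the median was -1.45, 9 of 9 were lower, and camera at the preset correlation gave p = 1.32e-11 (p = 0.0287 with an estimated correlation). Among these 9, Ear1 was at -2.12 ± 0.41 (SE, n = 4 per group), Epx, the eosinophil peroxidase, at -2.71 ± 0.60 with 1 of 4 mutant arrays well above background, and Ccr3, the eotaxin receptor, at -0.86 ± 0.54. These 9 are no independent check: Ear1, Epx, Ear10 and Ear6 stood among the ranked genes, and Ear1, Ear6 and Ear10 are paralogs of Ear2 whose probes may read it. Macrophages and other granulocytes make some of these transcripts, so the source of the fall stays open.

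By the authors' deposited table, 60 probes had an adjusted p under 0.05, 21 higher and 39 lower, with 46 named genes among them. All 17 genes that passed here were also past it in the authors' deposited table. Gata2 was at -2.16 with an adjusted p of 0.0732 in the authors' deposited table. Of the 60 probes in the authors' deposited table, 4 were of Xist or Y-linked genes (2 higher, 2 lower), and a further 5 without a name, all higher, lie within 100 kb of Xist. Of the hepatocyte list, 1 gene (Afp) was among the 60 in the authors' deposited table. Fgg, a fibrinogen gene outside that list, was at 2.46 with an adjusted p of 0.0103 in the authors' deposited table. A spread shared by all probes makes the p-value follow the size of the change, so genes that vary widely within a group may pass there. The same values with a spread per gene gave 52 genes, 12 of them higher, over 36557 features. The scanner files scaled by the median of each array gave 18 genes, 0 of them higher, over 40477 features. Scaling alone thus does not account for the higher genes. The authors' deposited table leaves out 5561 of the probes, and the effect of this was not tested. Embryos sexed beforehand, and counts of platelets, mast cells and eosinophils among the CD31-bearing cells of each embryo, would test whether cell numbers fall.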
